A study of Caldicellulosiruptor saccharolyticus with 4 samples.

How the data were processed

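RNA of the thermophilic, plant-degrading bacterium Caldicellulosiruptor saccharolyticus was measured on 4 spotted 2-colour arrays, 1 array per pair of substrates. Per the labels, each array carried 1 substrate in Cy3 (channel 1) and another in Cy5 (channel 2). The pairs formed a loop: poplar with xylose, switchgrass with poplar, glucose with switchgrass, and xylose with glucose. Each of the 4 substrates was therefore on 2 arrays, once in each dye. Nothing in the labels says that the 2 arrays of a substrate held separate cultures, so the p-values measure only the spread between these hybridisations, which may be technical.

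Per the file headers, the deposited scanner output gave the mean intensity of each spot and of its local background in each channel, neither background-corrected nor normalized. A deposited signal-to-noise score per spot was not used. The scanner software is not given in the sources used here. The authors also deposited a table of log2 values for 2679 genes. Against uncorrected log2 ratios of channel 1 over channel 2, with each gene's mean over the loop removed, its columns had slopes from 0.962 to 0.988 and Pearson r from 0.980 to 0.991 across genes. The 4 values of a gene in it summed to 0 within 1e-09. Its column medians were 0.05 for poplar with xylose, 0.01 for switchgrass with poplar, -0.11 for glucose with switchgrass and -0.02 for xylose with glucose. Its scale and direction were settled by this comparison, while the steps of its normalization stay unknown. It served as an alternative only. No column of samples outside the series was used.

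Each array held 15552 spots, of which 1587 were empty. Each of 2792 probes was printed 5 times, and they comprised 2695 locus tags and 97 gene models named by contig. 1 probe named for a gene of another organism was left out, and its signal was 0.925 to 1.27 times the median of the empty spots. Background was corrected with normexp and an offset of 50. Ratios were normalized within each array by loess, with empty and left-out spots at weight 0, and the log2 ratios of the 5 spots were averaged. The median SD among the 5 spots was 0.39 to 0.60 on the log2 scale.

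The log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no intercept, 3 substrate coefficients against glucose). The loop left 1 residual degree of freedom. A constant dye effect of a gene cancels from every difference between substrates in this fit and enters the residual. limma's prior carried 16.6 degrees of freedom and a residual SD of 0.62. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 2792 probes. The main comparisons were plant biomass minus sugars (mean of switchgrass and poplar minus mean of glucose and xylose), switchgrass minus poplar, and xylose minus glucose. The 4 remaining pairs of substrates were also tested. Design, the tests of genes and planned lists, the rule for named genes and most alternatives were fixed before the data were examined. Tests of gene order, of other splits of the substrates, of a dye effect and of brightness were chosen after the results had been seen.

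Probes were set against the empty spots, because the local background (median 56 or 62) lay far below them (median 462 to 775). A probe was taken as above background in a channel when the mean of its spots passed the 95th percentile of the empty spots. Where a substrate passed in neither of its channels, the brighter over the dimmer side is given as "at least N-fold", from channel values after loess and Aquantile scaling. Such a bound is open to dye bias. Some exceeded the fitted fold, in switchgrass minus poplar and in other comparisons, as for Csac_1079 in poplar minus xylose (8.65 against 6.18). None is printed for switchgrass minus poplar, and those printed for other comparisons lie below the fitted fold.

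The files do not pair locus tags with gene names, and no annotation was used here. Of 27 gene lists fixed in advance, 25 were defined by product words and could not be applied, and 2 were defined by locus range, the cellulase locus and the xylan locus. Another 8 groups of published function were added by locus tag from general knowledge of this genome, after their values had been seen. They are therefore not independent evidence of any direction. Other tags looked at in the same step were given no function, because their identity was unsure. The naming rule took the 8 largest called genes each way in the main comparisons, the 3 largest in the other pairs, and the members of the lists. Because identities are mostly missing, at most 2 tags of unknown function each way are printed per comparison. Lists of at least 4 genes were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The preset treats the genes of a list as nearly independent, which neighbouring genes need not be. Adjustment was over the 2 planned lists and, separately, over the added ones. Runs of at least 4 neighbouring measured tags, all at least 2-fold apart in 1 direction, were compared with 10000 shuffled gene orders.

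Alternatives covered background correction, normalization, spot averaging, dim probes, variance moderation, the model, the authors' table and each array left out. The dim filter removed the lowest 25% of probes by mean brightness. The separate-channel model used statmod 1.5.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

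The fit was tested on simulated data for biomass minus sugars, with 2792 probes, 200 of them changed, and 20 simulations. With array noise as the error, 14.8% of changes of 1 log2 unit, 80.6% of 2 units and 99.3% of 3 units were recovered, and 5.78% of calls were false. With a dye effect as the error, 0.0676%, 98.6% and 100% were recovered, and 0% of calls were false. All simulations assumed the prior degrees of freedom that limma estimated from these arrays. They also gave both plant substrates the same change, left the sugars alike and drew errors independently between genes. The rates may therefore not hold for the real data.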

Results

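Transcript levels of Caldicellulosiruptor saccharolyticus, a bacterium that grows on plant cell wall material at high temperature, were measured after growth on glucose, xylose, poplar or switchgrass. Per the labels, cells were subcultured 7 times on each substrate at 0.5 g per liter, grown at 70 °C and collected in mid-logarithmic phase. The sample labels give a culture volume of 0.4 liter, and the series text gives another volume. The series text names transporters and central carbon metabolism as the subject. 4 arrays were hybridised, 1 for each pair of neighbours in the loop, with no second array of any pair. The number of arrays limits the precision of every value.

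Signal over the empty spots differed among the channels. The share of probes above the empty spots was lowest for poplar in Cy3 on the poplar and xylose array (38.5%) and highest for xylose in Cy3 on the xylose and glucose array (77.5%). Of 2792 probes, 771 were above the empty spots in all 8 channels and 410 in none. The labels were checked by the correlation across genes of the 2 channels labelled with 1 substrate. It was 0.50 for poplar, 0.08 for xylose, -0.004 for switchgrass and -0.29 for glucose, above the value with channels exchanged in 4 of 4 cases (-0.33, -0.27, -0.64 and -0.53). The exchange was made on both arrays of a pair at once, so an exchange on a single array was not tested. The 2 glucose channels were negatively correlated, so this check of the labels is weak. The sum of the 4 log2 ratios around the loop, which is 0 without error or dye effect, had a median of -0.01 and an SD of 1.35 across genes. The residual held 17.3% of the variation of the ratios. Since it is 1 of the 4 degrees of freedom of the ratios, noise alone would leave about 1 part in 4 there. The 17.3% is therefore no measure of how well the substrates account for the ratios.

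The first comparison set growth on plant biomass against growth on simple sugars. The xylan locus, Csac_2404 to Csac_2411, known for xylan-degrading enzymes, rose on plant biomass in 8 of 8 genes, with a median log2 difference of 2.03. Csac_2406 rose most within it, by 2.50 ± 0.47 (SE), which is 5.65-fold (limma adjusted p = 0.0102), with 3.68 without the poplar and xylose array and 1.32 without the glucose and switchgrass array. In the cellulase locus, Csac_1076 to Csac_1080, known for multidomain cellulases and mannanases, 3 of 5 genes rose, with a median of 1.77. Csac_1080 rose by 3.30 ± 0.44, or 9.82-fold (adjusted p = 0.000926), with 2.63 and 3.96 when these arrays were left out. In the same locus Csac_1076, not above the empty spots on either sugar, was at least 2.47-fold higher on biomass but not called (limma adjusted p = 0.133), and Csac_1078 stood at 0.93 ± 0.43 (adjusted p = 0.432). Adjusted over the list alone, 8 of 8 and 5 of 5 genes rose. On both arrays that pair a plant substrate with a sugar (the direct arrays), which alone determine this fitted difference, all 8 and all 5 genes were higher on the plant substrate. By camera at the preset correlation of 0.01, the xylan locus passed at an adjusted p of 1.91e-17 and the cellulase locus at 4.56e-10. These values are too small if the neighbouring genes of a locus vary together. With an estimated correlation, both had an adjusted p = 0.195, and by fry the values were 0.0846 and 0.0228. With 1 residual degree of freedom the estimated correlations were 1 and -0.2, at the ends of their range. Neither the preset nor the estimate therefore gives a firm camera p for a locus. With 1 array left out at a time, the median of the xylan locus ran from 1.82 to 2.31 and that of the cellulase locus from 1.58 to 1.79. Only the direct arrays can move these medians. Leaving out 1 or the other shifts a gene by the same amount in opposite directions, so these are not separate checks. Over the alternatives in processing these medians ran from 1.03 to 2.11 and from 1.00 to 1.77. Neither locus had a called gene without background correction, with plain subtraction or with spot medians. The xylan locus had 0 of 8 genes above the empty spots in all 8 channels, and the cellulase locus 1 of 5.

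**Figure D1:**
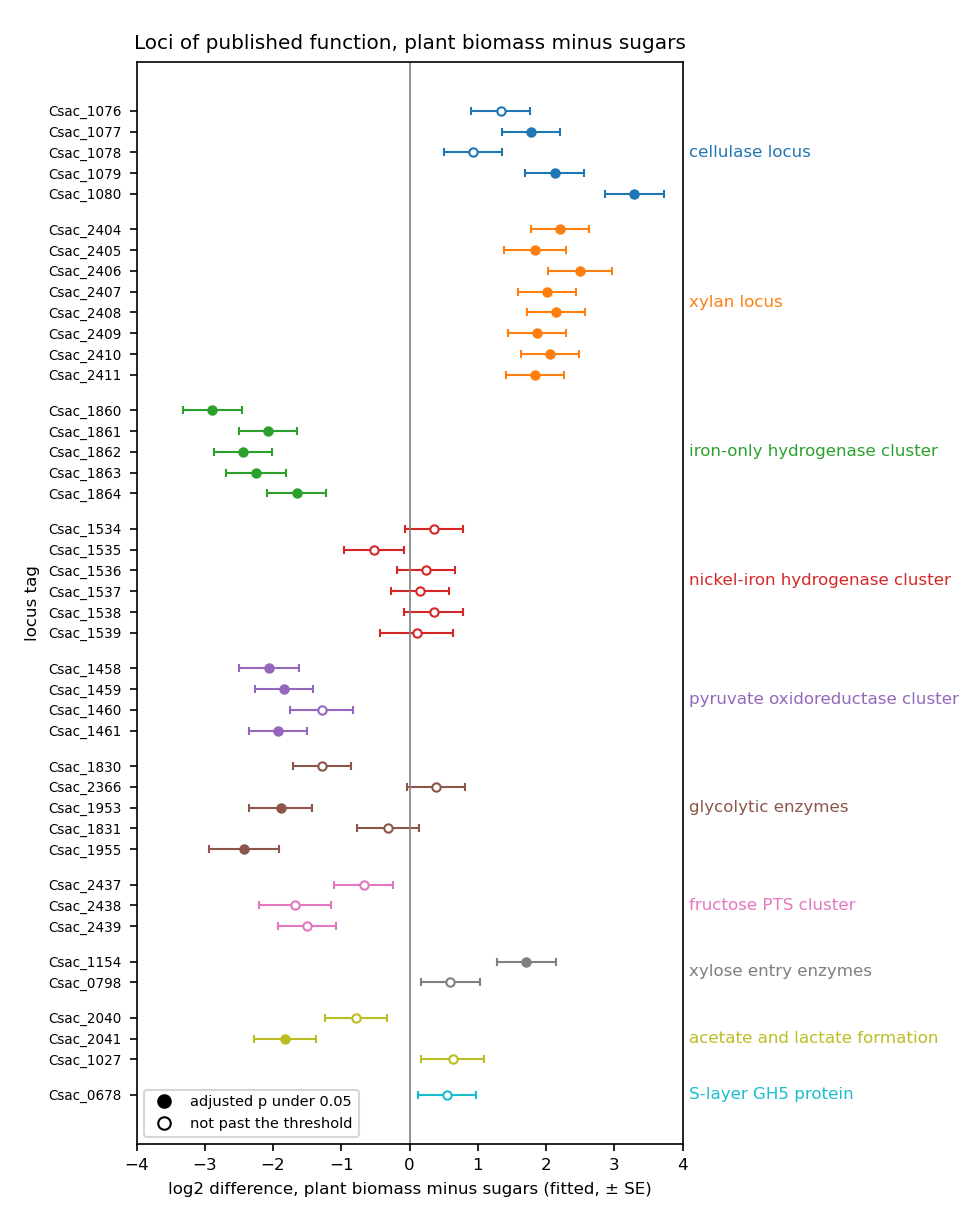
Fitted log2 difference (x axis, ± SE) between plant biomass and sugars for each locus tag of the 2 planned loci and the 8 groups added later (y axis), with filled points for an adjusted p under 0.05. All 13 genes of the xylan and cellulase loci lie above 0, and all 5 of the iron-only hydrogenase cluster lie below it.

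Among the groups added after their values were seen, the iron-only hydrogenase cluster, Csac_1860 to Csac_1864, which makes hydrogen from fermentation electrons, fell on plant biomass in 5 of 5 genes, with a median of -2.25, and 4 of 5 were lower on both direct arrays. Csac_1860 fell by 2.89 ± 0.44 (limma adjusted p = 0.00212), with -3.54 without the poplar and xylose array and -2.23 without the glucose and switchgrass array. The pyruvate oxidoreductase cluster, Csac_1458 to Csac_1461, which turns pyruvate into acetyl-CoA, fell in 3 of 4 genes, with a median of -1.88. The nickel-iron hydrogenase cluster, Csac_1534 to Csac_1539, had 0 of 6 genes called and a median of 0.20. Of 5 glycolytic enzymes, Csac_1953, glyceraldehyde-3-phosphate dehydrogenase, fell by 1.89 ± 0.47 and Csac_1955, pyruvate phosphate dikinase, by 2.42 ± 0.51. Without the poplar and xylose array these stood at -0.75 for both, and without the glucose and switchgrass array at -3.03 and -4.09. Only 1 of the 5 was lower on biomass on both direct arrays, and on the glucose and switchgrass array Csac_1953 and Csac_1955 were higher on switchgrass. Csac_1830, Csac_2366 and Csac_1831 did not pass. Csac_1154, xylose isomerase, rose by 1.71 ± 0.43, with 1.18 and 2.24 when those arrays were left out in the same order, and Csac_0798, xylulokinase, stood at 0.60 ± 0.43. Neither was higher on biomass on both direct arrays, and Csac_1154 stood at -0.89 in poplar minus xylose against 4.31 in switchgrass minus glucose. Csac_2041, phosphotransacetylase, fell by 1.82 ± 0.46, with -2.80 and -0.84 when the same arrays were left out. Csac_2040, acetate kinase, and Csac_1027, lactate dehydrogenase, did not pass, nor did the 3 genes of the fructose phosphotransferase cluster, Csac_2437 to Csac_2439, or Csac_0678, an S-layer glycoside hydrolase. By camera the hydrogenase and pyruvate oxidoreductase clusters passed at adjusted p of 1.33e-11 and 3.23e-07, and glycolysis at 0.00139. With an estimated correlation the adjusted p values were 0.236, 0.236 and 0.246. Because the groups were added after their values were seen, these p-values are not independent tests.

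Over all probes, 75 differed between plant biomass and sugars (34 higher and 41 lower on biomass), and 301 had an unadjusted p under 0.05. Of the 75, 61 went in the called direction on both direct arrays, and the rest did so on only 1 of them. The largest called tags of unknown function were Csac_0134, at 4.00 ± 0.68, and Csac_1182, at 3.64 ± 0.46, among those that rose. Csac_1032 fell by 3.55 ± 0.51 and Csac_2205 by 3.03 ± 0.47. Without the poplar and xylose array these 4 values were 0.84, 2.60, -1.86 and -1.81, and without the glucose and switchgrass array 7.16, 4.67, -5.24 and -4.25. In a count with no test, 261 probes were at least 2-fold apart, 632 without the poplar and xylose array and 551 without the glucose and switchgrass array. The number of calls was 0 without background correction, with plain subtraction or with spot medians, 2 without the dimmest probes and 7 with median centring. It was 218 with trended, robust moderation and 322 with spots as correlated values. Only 36 of the 75 were among the 218, while all 75 were among the 322. The 2 arrays that pair a plant substrate with a sugar did not correlate positively across genes (Pearson r -0.05, Spearman rho -0.05), and genes are not independent replicates. Of 151 genes at least 2-fold apart on both arrays, 45.0% went the same way. A gene-specific dye effect pushes these values down, since biomass was in opposite dyes. A constant dye effect cancels from fitted differences. Between these, Pearson r was 0.236 for poplar minus xylose with switchgrass minus glucose, and 0.342 for poplar minus glucose with switchgrass minus xylose. Array error raises the first value. Its covariance was 0.145, and array error alone would add 0.114 if the whole residual were array error. For the second the covariance was 0.193, to which array error adds nothing.

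**Figure D2:**
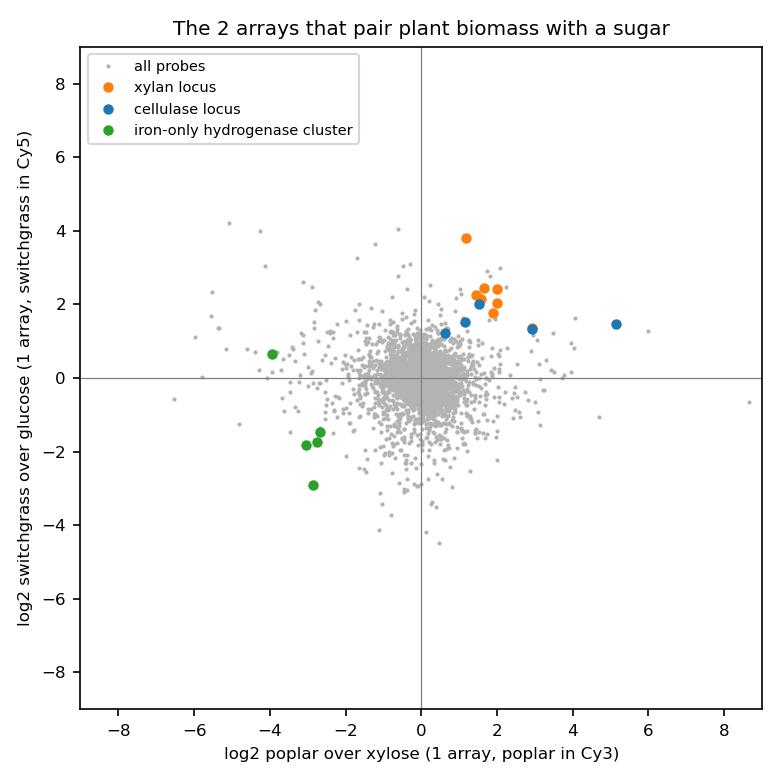
Log2 ratio of poplar over xylose on its array (x axis) against switchgrass over glucose on its array (y axis) for 2792 probes. The probes show no positive correlation (Pearson r -0.05), while all 8 xylan locus genes and all 5 cellulase locus genes are above 0 on both axes.

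The second comparison set switchgrass against poplar. No gene of either planned locus was called. The xylan locus had a median log2 difference of 0.03 (-0.05 to 0.35 with 1 array left out) and the cellulase locus of -0.44 (-0.45 to 0.24, so its direction was not stable). Csac_1080 stood at -1.45 ± 0.54 (limma adjusted p = 0.643). Their camera adjusted p values were 0.749 and 0.191. Among the added groups 0 genes were called, with Csac_2366, pyrophosphate-dependent phosphofructokinase, at 2.35 ± 0.52 (adjusted p = 0.0558) and Csac_1154 at 2.28 ± 0.53 (adjusted p = 0.0661). The pyruvate oxidoreductase cluster had a median of 0.97 and glycolysis of 1.65, with camera adjusted p of 0.00121 and 0.0136 but an adjusted p = 0.442 with an estimated correlation for both. With 1 array left out these medians ran from 0.71 to 1.44 and from 0.81 to 2.81. The hydrogenase clusters had medians of 0.05 (iron-only) and 0.21 (nickel-iron), with camera adjusted p of 0.25 and 0.402. The added groups were chosen after their values had been seen, so their camera p-values are not independent tests.

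Of all probes, 14 differed between the plant substrates, 9 higher and 5 lower on switchgrass, and 126 had an unadjusted p under 0.05. Csac_0692 rose on switchgrass by 4.90 ± 0.53, or 29.9-fold (limma adjusted p = 9.45e-05), and Csac_0445 by 3.34 ± 0.53. Csac_0222 and Csac_0995 fell on switchgrass, where neither was above the empty spots (adjusted p = 0.00596 for both). Without the switchgrass and poplar array, Csac_0692 was at 4.16 and Csac_0445 at 4.22, while the log2 value of Csac_0222 shifted by 0.65 and that of Csac_0995 by -1.33. The tags Csac_0992 to Csac_0995 formed a run lower on switchgrass, with 2 of 4 called and 3 of 4 not above the empty spots there. In a count with no test, 174 probes were at least 2-fold apart, and 1025 without the switchgrass and poplar array. The number of calls was 0 without background correction, with plain subtraction or with spot medians, 1 with median centring or without the dimmest probes, 85 with trended, robust moderation and 95 with spots as correlated values. Of the 14, 11 were among the 85.

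The third comparison set xylose against glucose. Csac_1154, xylose isomerase, rose on xylose by 2.92 ± 0.53, or 7.54-fold (limma adjusted p = 0.00357), while Csac_0798, xylulokinase, stood at 0.57 ± 0.53 (adjusted p = 1.00). Csac_1955, pyruvate phosphate dikinase, rose by 3.78 ± 0.62 (adjusted p = 0.00181). Csac_1864 of the iron-only hydrogenase cluster rose by 2.33 ± 0.53 and Csac_1461 of the pyruvate oxidoreductase cluster by 2.09 ± 0.52. Without the xylose and glucose array these 4 called genes stood at 2.12, 6.29, 3.02 and 1.93, and Csac_1955 stood at 2.95 without any 1 of the others. The cellulase and xylan loci had 0 genes called, with medians of -0.26 and 0.05 and camera adjusted p of 0.637 and 0.772. Over the settings the median of the cellulase locus ran from -0.46 to -0.02 and that of the xylan locus from -0.13 to 0.12. With 1 array left out they ran from -0.01 to 0.03 and from -0.13 to 0.49. By camera the iron-only hydrogenase cluster passed upwards at an adjusted p of 2.81e-05, and the nickel-iron hydrogenase cluster (downwards), the pyruvate oxidoreductase cluster and glycolysis passed at 0.0152. With an estimated correlation all 4 had an adjusted p = 0.244. These 4 groups were added after their values had been seen, so none of their camera p-values is an independent test.

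Of all probes, 85 differed between the sugars, 63 higher and 22 lower on xylose, and 259 had an unadjusted p under 0.05. The region Csac_0240 to Csac_0243 held the highest values. Csac_0240 was at least 42.7-fold higher on xylose, since it was not above the empty spots on glucose (limma adjusted p = 4.50e-07). Csac_0242 rose by 5.71 ± 0.71. A second region, Csac_0991 to Csac_0995, rose in 5 of 5 genes, of which 3 were not above the empty spots on glucose. On glucose, Csac_0134 was higher, with a xylose minus glucose value of -4.53 ± 0.83, as was Csac_1021, at -3.97 ± 0.52. Without the xylose and glucose array Csac_0242 stood at 9.19 and Csac_0134 at -9.26, and the log2 value of Csac_0240 shifted by 1.12. Without any 1 of the other arrays Csac_0242 stood at 4.55 and Csac_0134 at -2.95. In a count with no test, 315 probes were at least 2-fold apart, and 1041 without the xylose and glucose array. The number of calls was 0 without background correction, 3 with plain subtraction, 21 with spot medians, 31 without the dimmest probes, 35 with median centring, 193 with trended, robust moderation and 249 with spots as correlated values. Of the 85, 48 were among the 193.

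The remaining pairs set each plant substrate against each sugar. Poplar against xylose gave the most calls, 128 (45 higher and 83 lower on poplar), with 368 at an unadjusted p under 0.05. The iron-only hydrogenase cluster fell in 5 of 5 genes on poplar (median -3.16), 4 of 8 xylan locus genes rose (median 1.95), and 2 of 5 cellulase locus genes rose (median 1.63). The largest values were those of Csac_0134, which rose by 7.08 ± 0.83, and Csac_1032, which fell by 5.68 ± 0.63, with 2.34 and -3.15 without the poplar and xylose array and 8.65 and -6.53 without any 1 of the others. Csac_1182 rose by 5.47 ± 0.56 and Csac_1606 fell by 5.53 ± 0.53, with 3.91 and -4.77 without the poplar and xylose array. Switchgrass against xylose gave 68 calls, 27 higher and 41 lower, with 305 unadjusted. There the hydrogenase cluster fell in 4 of 5 genes (median -3.03), and 1 of 8 xylan locus genes and 1 of 5 cellulase locus genes rose (medians 2.11 and 1.88). Csac_0995 was at least 20.5-fold lower on switchgrass than on xylose (limma adjusted p = 0.00101), and its log2 value shifted by 0.89 either way with 1 array left out.

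Switchgrass against glucose gave 21 calls, 10 higher and 11 lower, with 233 unadjusted. Csac_1154 rose by 4.31 ± 0.53 on switchgrass, and by 5.10 without the glucose and switchgrass array, and 3 of 8 xylan locus genes rose (median 1.98). There 0 of 5 cellulase locus genes were called (median 1.62, with 4 of 5 adjusted over the list alone), and 1 of 5 genes of the iron-only hydrogenase cluster fell (median -1.54), with Csac_1864 at 0.42. Csac_0956 fell by 3.29 ± 0.63, but stood at -0.74 without the glucose and switchgrass array and at -4.13 without any 1 of the others. Poplar against glucose gave 6 calls, 4 higher and 2 lower, with 133 unadjusted. Csac_1080 rose by 3.24 ± 0.62 on poplar, and 0 of 8 xylan locus genes were called (median 2.01, with 8 of 8 adjusted over the list alone). The iron-only hydrogenase cluster had 0 of 5 genes called there (median -1.57). These 2 pairs and switchgrass against xylose had 0 calls without background correction, with plain subtraction and with spot medians. Poplar against xylose had 0, 0 and 35.

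Neighbouring genes were apart together, by a test chosen after the results had been seen. In biomass minus sugars, 58 genes lay in 11 runs of at least 4 neighbouring tags, 2 runs higher and 9 lower on plant biomass, against at most 8 genes in any of 10000 shuffled orders (permutation test, p = 1e-04, the smallest the shuffles can give). The higher runs were Csac_2404 to Csac_2414, which extends beyond the xylan locus by 3 tags, and Csac_2416 to Csac_2419. They averaged 2.01 and 2.38 on the log2 scale, with 9 of 11 and 4 of 4 genes called. The lower runs included the hydrogenase cluster Csac_1860 to Csac_1864 (5 of 5 called), Csac_1458 to Csac_1461 (3 of 4), Csac_0955 to Csac_0958 (3 of 4) and Csac_1950 to Csac_1956 (3 of 7). Of the rest, Csac_2283 to Csac_2288 had 2 of 6 called, Csac_2207 to Csac_2210 had 1 of 4, and the remaining 3 runs had 0. Runs held 8 genes in switchgrass minus poplar, against at most 5 in any shuffled order, and 42 in xylose minus glucose, against at most 9, with a permutation test p = 1e-04 for both.

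**Figure D3:**
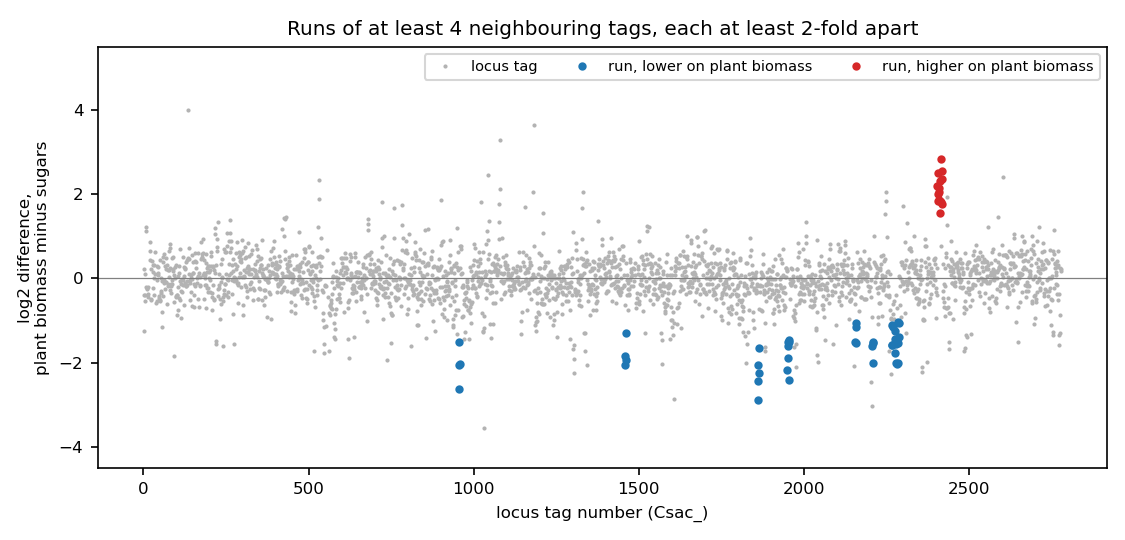
Fitted log2 difference between plant biomass and sugars (y axis) for each measured locus tag in order of its number (x axis), with the runs of at least 4 neighbouring tags in colour. The 2 higher runs lie side by side at Csac_2404 to Csac_2419, and the 9 lower runs lie at tags from Csac_0955 to Csac_2288.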

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

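The split tests and the dye test were chosen after the results had been seen, and the test of signal near the empty spots was chosen before. The plant over sugar effect was compared between pairs of substrates that differ in both the plant and the sugar. A difference may come from either, so it does not show that the effect depends on the plant. The comparison of the plants alone, switchgrass minus poplar, called 14 genes. For 99 genes, poplar over xylose differed from switchgrass over glucose by limma's test of the difference (adjusted p under 0.05, 319 unadjusted). This is the split of switchgrass and xylose against poplar and glucose, with 76 genes higher on switchgrass and xylose and 23 lower. For 12 genes, poplar over glucose differed from switchgrass over xylose (127 unadjusted), with 3 higher on switchgrass and glucose and 9 lower. The 99 exceed the 75 called for biomass against sugars, with 25 genes in both, and the median SE of that split was smaller (0.30 against 0.43). Without background correction the 99 became 5 and the 12 became 0, and with spot medians they became 21 and 0.

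Csac_0692 led the first split, 20.8-fold higher on switchgrass and xylose (log2 4.38 ± 0.31, adjusted p = 1.03e-07), with fitted levels against the mean of the 4 substrates of 2.39 on switchgrass, 1.99 on xylose, -1.86 on glucose and -2.52 on poplar. Csac_2372 was high on xylose alone (levels 3.55 on xylose, -0.29 on switchgrass, -1.55 on glucose and -1.71 on poplar), so the split gathers more than 1 pattern. A constant gene-specific dye effect cancels from this split, so it could not be the source of these calls, whatever the following correlation. The split was also estimated from the arrays with switchgrass and xylose in Cy3 and from those with them in Cy5. A dye effect alone would give a correlation across genes at or below 0 between these estimates, and the observed r was 0.38 (bootstrap interval 0.32 to 0.44). The interval resamples genes, which are not independent replicates, and does not measure the spread between arrays. Of the 99 genes, 42.4% were above the empty spots in all 8 channels (exact interval 32.5% to 52.8%), against 27.6% of all probes. The share of all probes also counts the 410 that were above them in no channel, so the higher share decides little. For the called genes not above the empty spots in every channel, noise near the empty spots stays open. Differences between cultures other than the substrate were not tested and stay open, because the labels do not say whether any substrate had a second culture.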

How the results depend on the processing

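Counts of called genes depended on the processing. None of the 55 results for called, named genes changed sign, but they had been picked because they were called, so a change of sign was unlikely. Aquantile scaling, trended moderation, spots as correlated values and the dim filter also leave the fitted value of a gene as it is. Calls for biomass - sugars, switchgrass - poplar, xylose - glucose, poplar - xylose, poplar - glucose, switchgrass - xylose and switchgrass - glucose numbered 75, 14, 85, 128, 6, 68 and 21. Without background correction they were 0 in all 7, with plain subtraction 0, 0, 3, 0, 0, 0 and 0, with median centring 7, 1, 35, 75, 0, 19 and 2, with spot medians 0, 0, 21, 35, 0, 0 and 0, and without the dimmest 25% 2, 1, 31, 79, 0, 13 and 2. They were 218, 85, 193, 281, 85, 210 and 160 with trended, robust moderation, 322, 95, 249, 404, 105, 312 and 218 with spots as correlated values, and 137, 16, 137, 255, 23, 140 and 38 with the separate-channel model. With the empty spots as background, chosen after seeing the data, they were 60, 10, 72, 119, 0, 61 and 9. The larger counts with trended, robust moderation do not hold all calls of the reported fit. In the same order, they held 36, 11, 48, 70, 3, 37 and 9 of those calls. Aquantile scaling leaves the ratios as they are and tests nothing here. The prior degrees of freedom were 16.6 in the reported fit, 2.87 without background correction, 3.03 with plain subtraction, 6.19 with spot medians, 8.39 without the dimmest 25% and 14.3 with median centring, infinite with trended moderation, 6.58 with spots as correlated values and 4.19 with the separate-channel model. The cause of the changes was not tested.

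Counts of genes at least 2-fold apart in the first 3 comparisons were 261, 174 and 315, with 137, 74 and 192 without background correction, 149, 82 and 200 with plain subtraction and 164 and 92 in the authors' table for the first 2 comparisons (223 in the third). With 1 array left out they ranged from 261 to 632, from 201 to 1025 and from 344 to 1041. By the loop design, a difference whose direct array is left out rests on a sum of the other ratios. Such a sum carries more error and keeps a dye effect, which raises the count. The 261 holds without an array that does not enter biomass - sugars. Whether the design accounts for the whole rise was not tested. The settings with 1 array left out and the authors' table leave no residual degree of freedom, so they give no test. Lists called in biomass - sugars numbered 2, 0 with an estimated correlation and 1 with fry. The agreement of the 2 arrays that pair a plant substrate with a sugar was -0.05, and -0.0948 with median centring. The SD of the loop sum was 1.35, with 0.89 without background correction, 0.92 with plain subtraction, 1.59 with median centring and 1.43 without the dimmest 25%.

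Among these 55 results, leaving out 1 array moved a value by more than its SE in 103 cases and not in 117. The 117 include cases that could not move, since the switchgrass and poplar array and the xylose and glucose array do not enter biomass - sugars. For 2 substrates that share an array, leaving out any 1 of the other arrays gives the same value, so these cases are not separate checks. The authors' table moved a value by more than its SE in 24 cases and not in 15. The adjusted p missed the threshold in 55 without background correction, 54 with plain subtraction, 48 with spot medians, 38 without the dimmest 25%, 33 with median centring, 23 with trended moderation, 10 with empty spots as background, 2 in the separate-channel model and 0 with spots as correlated values. The xylan locus kept a positive median in biomass - sugars, from 1.03 to 2.11 over 11 settings, the cellulase locus from 1.00 to 1.77, and the iron-only hydrogenase cluster a negative one, from -2.30 to -1.75. The alternative that keeps marked spots was not run, because no column marks spots. The fit already pairs the 2 substrates of an array through their ratio, but each pair of substrates has a single array, so no pair was replicated.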

Other observations

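The test of print blocks was chosen before its result was seen, and the tests of gene order and of brightness after. Beyond the named loci, the lower runs on plant biomass included Csac_2275 to Csac_2279 and Csac_2283 to Csac_2288, with mean log2 differences of -1.60 and -1.51 and fitted levels lowest on switchgrass (-1.30 and -1.23), with 0 of 5 and 2 of 6 genes called. In xylose minus glucose, Csac_0860 to Csac_0863 averaged -2.10, with 2 of 4 genes called, and Csac_0971 to Csac_0978 averaged 1.95, with 4 of 8 called. The contig gene model Contig150_gene772, outside the authors' table, was higher on plant biomass by 2.29 ± 0.54 (limma adjusted p = 0.0271). Of the 97 contig gene models, 20 were above the empty spots in all 8 channels.

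The runs in biomass minus sugars were set against 2 technical explanations. Chance order was excluded at the resolution of the shuffles, with a share of 1e-04, the smallest they can give. Printing in the same block of the array was rare inside the runs, as 1 of 47 neighbouring pairs inside the runs, or 2.13% (exact interval 0.0539% to 11.3%), shared a block, against 2.38% of all neighbours. Joint transcription of neighbouring genes may underlie the runs, as a hypothesis that was found and tested on the same data and that the files hold no direct test of.

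The xylan locus was set against a brightness trend left by the normalization. Its median of 2.03 lay above 10000 lists of 8 genes matched on brightness, whose medians reached 0.68 and had a central 95% range of -0.56 to 0.32. Cross-hybridisation and differences between cultures stay open as untested explanations, and no biological explanation beyond the substrate was tested.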
